A study of Homo sapiens with 32 samples.

How the data were processed

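The series holds 32 small RNA sequencing libraries of human body fluids from 22 donors, in 9 groups over 8 fluids. Per the labels' protocols, blood was drawn into EDTA tubes, while feces, vaginal secretion, menstrual secretion and perspiration were taken up on cotton swabs. RNA of 6 fluids was extracted with the Qiagen miRNeasy kit, urine with a Norgen Biotek kit and feces with a MoBio kit. Libraries were made with the NEBNext Multiplex Small RNA Library Prep Set 1, all per the labels' protocols. Extraction kit and fluid therefore coincide for urine and for feces. No sequencing batch is given in the sources used here.

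The values analysed were estimated counts of reads per mature miRNA, as the authors deposited them, in 1 table of 662 entries by 32 libraries. The submitters' processing notes name Bowtie 1.0, Partek and the GRCh38 build, without their role or order, and trimming, mismatch limits and the miRNA annotation are not given in the sources used here. Of the 21184 values 583 (2.75%) in 43 entries were fractional, so all values were rounded to whole numbers before any count model. All columns were matched to a library by name. Some entries are not separate measurements, but counts include each. In 9 pairs the values were equal in at least 90% of libraries with either above 0, among them miR-103a-3p and miR-103b, miR-203a and miR-203b-5p, miR-423-5p and miR-3184-3p, miR-374b-5p and miR-374c-3p, and miR-122-5p and miR-3591-3p. In 3 more pairs, miR-24-3p and miR-3074-5p, miR-423-3p and miR-3184-5p, and miR-486-3p and miR-486-5p, the ratio of the values was the same in every library with at least 20 reads of both (highest over lowest ratio under 1.01). The 2 arms of miR-486 stood at 3.26, so neither arm was measured alone.

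Library totals went from 1413 to 1092980 reads. With such totals a count of 0 allowed up to 3 counts, and shares of miR-451a in single libraries have 95% exact (Clopper-Pearson) binomial intervals. These cover counting error only. Pairs of libraries within groups were compared by chi-square over entries: none of 43 pairs held identical values, and the chi-square per degree of freedom was 1.46 to 251, so each library was kept as 1 sample. Libraries of a group came from different donors, per the labels.

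Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (TMM factors of 0.339 to 2.50, quasi-likelihood fit and test, Benjamini-Hochberg adjustment, adjusted p under 0.05) in 1 fit of all 32 libraries and 9 groups, which shares 1 estimate of the spread. Entries were kept by filterByExpr with the groups, a minimum count of 10 and a minimum total of 15. This left 247 entries, which held at least 97.9% of the reads of every library. The common dispersion was 0.533. Each fluid was compared with the unweighted mean of the 7 other fluids, with the mean of both semen groups as 1 fluid. In addition 4 pairs of groups were compared, and a miRNA was called specific to a fluid if it was higher than in each of the 7 other fluids. Standard errors were the log2 fold change divided by the root of the quasi-likelihood F. An entry with 0 reads in all libraries of a further fluid could not be called lower than the mean of the other fluids by edgeR, a limit that was noticed after the results were seen.

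The miRNAs named were taken by a rule. Per fluid it took the 10 largest and 5 most negative log2 fold changes among entries with an adjusted p under 0.05, a mean of at least 100 CPM on the higher side and a direction shared by every library of the fluid against the median of the other libraries. Per pair of groups it took the 10 largest and 10 most negative with a mean of at least 100 CPM in the higher group. It also took up to 10 specific miRNAs per fluid by the smallest of the 7 folds, the 5 with the largest mean share per fluid, and members of the lists as examples. Other names are given as chosen after their values were seen.

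Lists of miRNAs stood for erythroid, leukocyte, endothelial and platelet, miR-200 family epithelial, squamous epithelial, epididymal (miR-888 cluster), testicular (miR-506 cluster), germ and multiciliated cell (miR-34/449), HOX cluster, gut and liver, kidney, stromal and smooth muscle, let-7, rRNA-, tRNA- or repeat-like, miR-320 and skeletal muscle miRNAs. They held 0 to 20 tested members, and miR-10a-5p is in both the HOX and the kidney list. Lists with at least 3 tested members were compared with all other tested entries by camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over 156 pairs of list and comparison. The similarity of libraries was the mean Spearman correlation of log2 CPM within groups minus that between groups, with a one-sided permutation test of 100000 permutations.

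The donor codes of the labels pair libraries across fluids, because the same 6 donors gave more than 1 fluid. Libraries of the same donor hardly deviated together: over 17 such pairs the mean correlation of their deviations from the group means was 0.0164 (-0.314 to 0.146), against -0.0006 over 436 other pairs, and the correlation estimated for the donor block in limma voom was 0.0914.

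The alternatives were RLE, TMMwsp or library size alone in place of TMM, no filter, a filter of 100 CPM in 3 libraries, DESeq2 1.42.0, limma voom without and with the donor as a block, the fluids extracted with the Qiagen kit alone, camera with an estimated correlation, fry, Pearson correlation, pairs of different donors alone, and leaving out each library in turn. Further ones were chosen after seeing the data: every library thinned to 1416 reads, no library under 5000 reads, no library with a high ratio of miR-486 to miR-451a reads, a term for those 9 libraries, 1 entry of each set that shares reads, and list tests on limma voom statistics. Those 9 libraries were all 4 of perspiration, all 4 of urine and vasectomized semen replicate 2, with ratios of 0.475 or more against 0.127 or less in the rest. Because the set was defined from the data and nearly coincides with 2 fluids, only the vasectomized semen libraries separate the term from the fluids.

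The steps were tested on simulated data with 200 entries changed per comparison. Only those passing the filter, 23 to 43 per comparison and fold, enter the shares recovered. Of entries changed 16-fold, 79.5% (31 of 39) were recovered in saliva against vaginal secretion, where 203 entries were tested, and 100% in menstrual secretion (37 of 37, 219 tested) and perspiration (31 of 31, 231 tested). Of entries changed 4-fold, 17.9% (7 of 39) were recovered in vasectomized semen against semen (198 tested) and 81.5% (22 of 27) in semen against the other fluids (222 tested). With no entry changed, 203 were tested per comparison. Called were 3 in blood, 1 in menstrual secretion against blood and 0 in 10 others. All 3 raised lists and 1 other were called, and 0 of 144 unchanged pairs of list and comparison. Relabeled real libraries gave a median of 31.

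Genomic positions of miRNA genes were looked up in the GENCODE 29 annotation of GRCh38 with Python 3.11.15: 166 of 173 miRNAs were placed. Figures were drawn with matplotlib 3.10.9.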

Results

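MicroRNAs (miRNAs) were measured by small RNA sequencing in 32 libraries of human body fluids met in forensic casework, and the question put to them was which miRNAs mark each fluid. The libraries came from 8 fluids: venous blood (n = 3), menstrual secretion (n = 4), vaginal secretion (n = 4), saliva (n = 4), urine (n = 4), feces (n = 4), perspiration (n = 4) and semen (n = 5). Semen was split into semen (n = 3) and semen from vasectomized donors (n = 2), called vasectomized semen. Within each group every library came from a different donor. Of the 22 donors, 6 gave more than 1 fluid. Urine and feces were each extracted with a kit used for no other fluid, so their values cannot be told apart from those of their kits.

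Depth differed widely between the fluids. The 3 blood libraries held 1032480, 1069500 and 1092980 reads assigned to miRNAs, while the median of the 29 other libraries was 15206. Feces held the fewest, from 1413 to 3597 reads. The other ranges were 4043 to 48974 reads in saliva, 4277 to 35694 in vaginal secretion, 5159 to 67421 in menstrual secretion, 7025 to 28206 in perspiration, 5395 to 123424 in urine, 23547 to 27080 in semen, and 109818 and 183852 in vasectomized semen. At least 10 reads were listed for 310 ± 8.72 miRNA entries in blood (SD, n = 3) and for 33.5 ± 12.7 in feces (SD, n = 4). A count of 0 therefore allowed a level of up to 3 counts per library. In CPM, which scale counts to a common library total, this was 2.74 in the deepest library and 2123 in the shallowest before TMM scaling, which all CPM given from here on include. These limits cover counting error only, because PCR copies are not independent molecules.

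The leading entry of each group took 8.42% to 37.0% of its reads. The red cell miRNA miR-451a made up 35.6% ± 2.08 of the reads of blood (SD, n = 3) and 37.0% ± 5.51 of those of feces (SD, n = 4). In saliva, menstrual secretion and vaginal secretion the leading miRNA was miR-21-5p, at 12.5% ± 5.01, 22.2% ± 11.1 and 23.0% ± 18.7 (SD, n = 4 each). miR-148a-3p led in semen with 26.5% ± 10.6 (SD, n = 3) and in vasectomized semen with 33.0% ± 9.84 (SD, n = 2). Keratinocyte miR-203a and the equal miR-203b-5p each held 17.1% ± 3.79 of perspiration reads, and miR-10b-5p 8.42% ± 6.11 of urine reads (SD, n = 4). miR-451a was read in every library: the 25 libraries outside blood and menstrual secretion held 49 to 1612 reads of it, and its share went from 0.181% in a semen library (95% exact Clopper-Pearson interval 0.134% to 0.239%) to 40.1% in a feces library (38.5% to 41.8%).

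**Figure D1:**
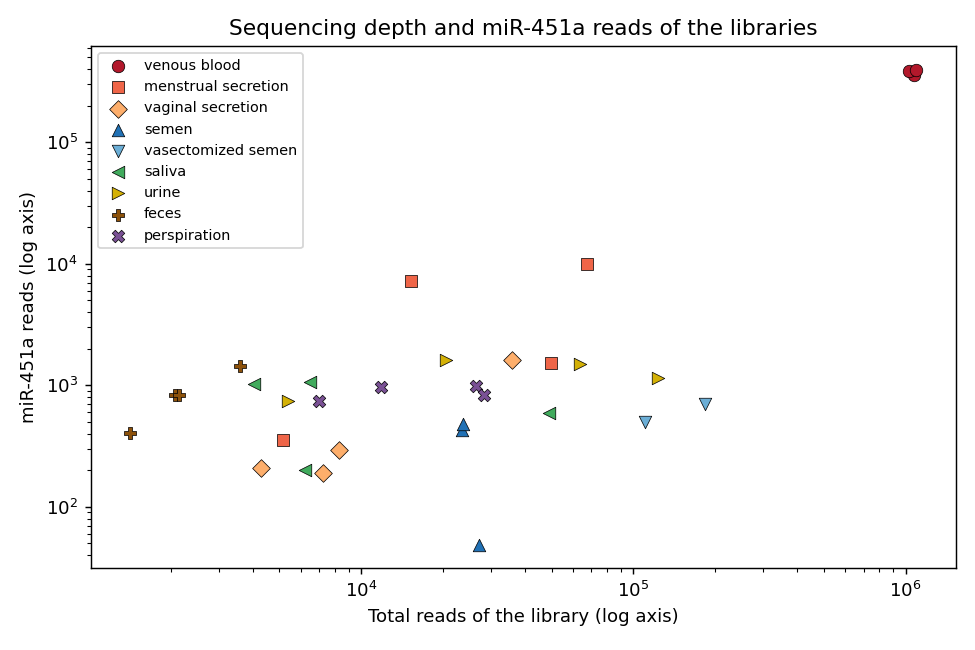
Reads of miR-451a (y axis, log scale) against all reads assigned to miRNAs (x axis, log scale), with each point 1 of the 32 libraries coloured by group. The blood libraries hold 1032480 reads or more and feces the fewest, 1413 to 3597, yet every library holds at least 49 reads of miR-451a.

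Libraries of the same fluid were more alike than libraries of different fluids. The mean Spearman correlation across miRNAs was 0.796 ± 0.107 within groups and 0.560 ± 0.133 between groups (SD over pairs of libraries), a difference of 0.237 with a one-sided permutation p = 1e-05 over 100000 permutations, the smallest they can give. Pairs of blood libraries were the most alike at a mean of 0.982, and pairs of feces libraries the least at 0.676. Among different groups, semen and vasectomized semen averaged 0.842, menstrual and vaginal secretion 0.732, and saliva and vaginal secretion 0.715. For 24 of the 32 libraries the most similar other library belonged to the same group. miRNAs are not independent replicates, so these correlations describe the libraries only.

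**Figure D2:**
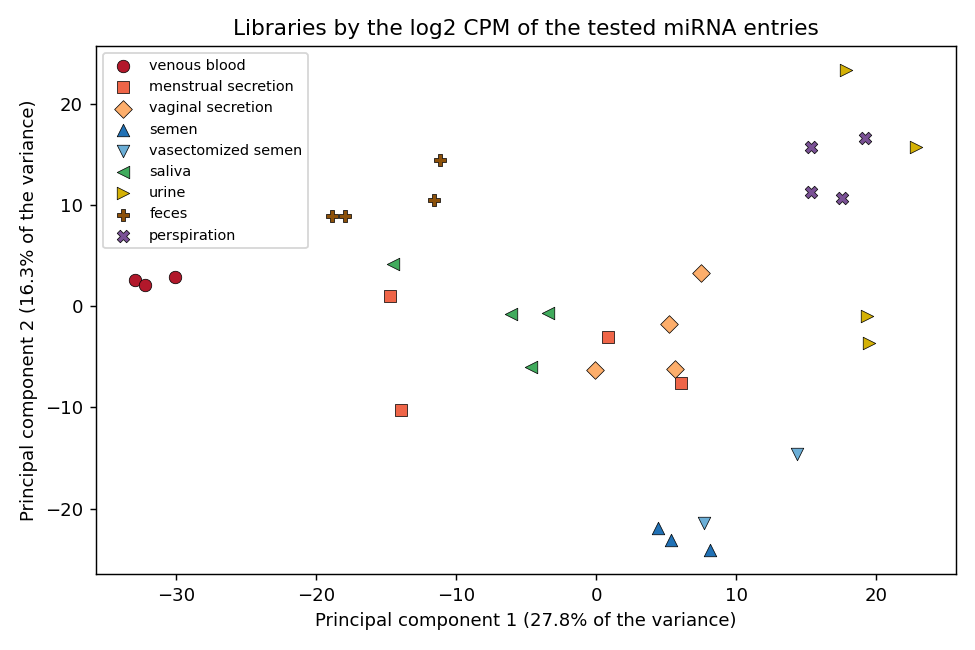
Principal components of log2 CPM, with component 1 (27.8% of the variance) on the x axis and component 2 (16.3%) on the y axis, and each point 1 of the 32 libraries coloured by group. Blood lies alone at -32.9 to -30.1 on component 1, while urine replicates 1 and 4 (15.7 and 23.3 on component 2) lie by perspiration (10.7 to 16.6) and apart from urine replicates 2 and 3 (-3.62 and -0.999), and menstrual secretion spans -14.8 to 6.03 on component 1.

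Each fluid was then compared with the mean of the 7 other fluids over 247 tested miRNA entries. Lists of miRNAs fixed before the data were examined, such as red cell, leukocyte or squamous epithelial miRNAs, were compared with all other miRNAs by camera. Of 156 pairs of list and comparison, 31 had an adjusted p under 0.05 with camera's preset correlation of 0.01, but only 1 did with an estimated correlation, the epididymal list in vasectomized semen. A list call given below therefore rests on the preset correlation, and the p with an estimated correlation stands beside it. An entry with 0 reads in every library of another fluid, which was true of 57 to 82 entries per comparison, could be called higher but not lower by edgeR, because the mean of the other fluids then has no lower limit. Over the 8 comparisons edgeR called such entries higher 154 times and lower 0 times, while limma voom, whose added offset places a count of 0 lower in a deep library than in a shallow one, called them higher 135 times and lower 105 times, 57 of these in blood.

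Venous blood held raised miR-144-3p, miR-126-3p, miR-17-5p and miR-20a-5p under all 4 scalings. miR-144-3p, which is transcribed together with miR-451a in erythroid cells, averaged 128260 ± 53662 CPM (SD, n = 3) against 15210 in feces, the next fluid, and its log2 fold change over the mean of the other fluids was 6.45 ± 0.55 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 3.4e-13). miR-126-3p, a miRNA of endothelium and platelets, rose by 5.18 ± 0.50 on the log2 scale (edgeR adjusted p = 4.7e-12). miR-17-5p and miR-20a-5p, products of 1 cluster transcript, rose by 4.92 ± 0.46 and 4.80 ± 0.40 (edgeR adjusted p = 4.5e-12 and 2.6e-13). The epithelial miRNAs miR-375 and miR-200a-3p had log2 fold changes of -9.50 ± 1.40 and -9.02 ± 1.31 (edgeR adjusted p = 1.4e-07 and 1.2e-07). With RLE the first 4 of these folds were 3.80, 2.52, 2.28 and 2.11, the smallest of the 4 scalings, and the last 2 were -12.31 and -11.76. MIR144 and MIR451A lie beside each other on the minus strand of chromosome 17 (GRCh38), at 28861533 to 28861618 and 28861369 to 28861440, in an exon of the long non-coding RNA gene AC024267.1. MIR126 lies in an intron of EGFL7 on chromosome 9, from 136670602 to 136670686.

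Of the 12 tested members of the erythroid list 11 rose in blood and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 5.4e-05; adjusted p = 0.508 with an estimated correlation). RLE scaling left 6 of them higher and made 1 lower. All 7 members of the miR-200 family, which marks epithelium, fell, among them miR-200b-3p with -8.05 ± 1.14, and 7 fell adjusted over the list alone (camera adjusted p = 7.7e-05; adjusted p = 0.409 with an estimated correlation). Of 6 squamous epithelial miRNAs 4 fell, and 4 adjusted over the list alone (camera adjusted p = 0.000416; adjusted p = 0.468 with an estimated correlation). Of 20 entries that resemble rRNA, tRNA or repeats, 6 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00959, 0.119 with RLE scaling; adjusted p = 0.508 with an estimated correlation). In the leukocyte list 3 of 10 rose, in the endothelial and platelet list 2 of 4, and in the let-7 family 6 of 10, with the same counts adjusted over each list alone. None of these 3 lists was called (camera adjusted p = 0.446, 0.262 and 0.234), and the median of the let-7 family went from 1.59 to -1.03 with RLE scaling and that of the leukocyte list from 0.38 to -2.21.

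In all, 124 of 247 entries differed in blood, 92 higher and 32 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with a median log2 fold change over all tested entries of 0.29. The split depended on scaling: RLE gave 21 higher and 73 lower with a median of -2.11, library size alone 51 higher and 46 lower with a median of -1.10, and TMMwsp 70 higher and 38 lower with a median of -0.29. All 32 lower calls and 21 of the 92 higher calls were made under all 4 scalings, and miR-451a itself, at 3.83 ± 0.52 (edgeR adjusted p = 3.1e-08), was not called with RLE (1.10, adjusted p = 0.181).

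Menstrual secretion held raised stromal and smooth muscle miRNAs. The mesenchymal miRNAs miR-199a-3p and miR-199b-3p reached 1290.1 ± 1619 and 1394 ± 1416 CPM (SD, n = 4), log2 fold changes of 4.46 ± 0.64 and 4.23 ± 0.61 over the other fluids (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.3e-06 for both). The smooth muscle miRNA miR-143-3p rose by 3.75 ± 0.57 and the myeloid miRNA miR-223-3p by 3.53 ± 0.52 on the log2 scale (edgeR adjusted p = 2.8e-06 and 1.5e-06). miR-3662 averaged 909 ± 1326 CPM (edgeR adjusted p = 5.9e-07, but 0.0892 with DESeq2), and its gene lies in an intron of HBS1L on chromosome 6, from 134979338 to 134979432. The red cell miRNAs depended on single libraries. miR-451a rose by 1.92 ± 0.54 (edgeR adjusted p = 0.00583), with adjusted p = 0.563 without menstrual secretion replicate 4, 0.227 with RLE, 0.142 with library size alone, and 0.176 with and 0.215 without the donor as a block in limma voom. miR-144-3p rose by 2.69 ± 0.58 (edgeR adjusted p = 0.000431, and 0.0647 without replicate 4).

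All 6 members of the stromal list rose in menstrual secretion, and 6 adjusted over the list alone (camera adjusted p = 0.000416; adjusted p = 0.409 with an estimated correlation), but 2 of these calls depended on the processing. miR-145-5p, with 0, 1, 16 and 0 reads, was not called without menstrual secretion replicate 3 (edgeR adjusted p = 0.875), semen replicate 2 or 3, urine replicate 2 or any blood library, nor with RLE (0.112), library size alone (0.0781), DESeq2 (0.644) or limma voom (0.642 with and 0.660 without the donor block). miR-199a-5p was not called by DESeq2 (adjusted p = 0.172) or limma voom (0.114 with and 0.113 without the block). All 6 squamous epithelial miRNAs rose, and 6 adjusted over the list alone (camera adjusted p = 0.00771; adjusted p = 0.568 with an estimated correlation). The squamous call was lost without menstrual secretion replicate 1 (adjusted p = 0.233) or replicate 2, and without replicate 1 miR-203a, miR-205-5p, miR-944 and miR-31-5p were no longer called (edgeR adjusted p = 0.141, 0.0871, 0.287 and 0.589). miR-205-5p was also not called by limma voom with the donor block (adjusted p = 0.136) or without it (0.147). In the erythroid list 6 of 12 rose, 7 adjusted over the list alone, and the list was not called (camera adjusted p = 0.164). The entries that resemble rRNA, tRNA or repeats ranked low although 0 of 20 were called (camera adjusted p = 0.00483, and 0.199 without replicate 3; adjusted p = 0.508 with an estimated correlation).

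In menstrual secretion 67 entries differed, 63 higher and 4 lower (edgeR), with a median log2 fold change of 0.57, which was 0.37 with RLE, 0.38 with TMMwsp and 0.19 with library size alone. Without replicate 1 the count was 25 and without replicate 3 it was 35, and limma voom called 31 with the donor as a block and 25 without it.

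Vaginal secretion held raised squamous epithelial miRNAs, some of which also rose in menstrual secretion, saliva and perspiration, and raised miR-210-3p, which is induced by low oxygen. miR-210-3p averaged 12312 ± 12386 CPM (SD, n = 4), a log2 fold change of 4.68 ± 0.52 over the other fluids (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.3e-09). miR-205-5p, a miRNA of squamous epithelium, rose by 4.13 ± 0.60 to 28338 ± 20486 CPM, and miR-203a by 3.43 ± 0.52 on the log2 scale (edgeR adjusted p = 5.7e-07 and 1.4e-06). miR-452-5p and miR-378c rose by 5.31 ± 0.59 and 4.15 ± 0.49 (edgeR adjusted p = 1.3e-09 and 4.5e-09). miR-193b-3p reached 6230 ± 6283 CPM and was higher than the mean of the other fluids (edgeR adjusted p = 3.2e-10). The next fluid, menstrual secretion, held 1169 CPM of it, and the direct comparison of both fluids did not call it. The liver and gut miRNA miR-192-5p was lower, at -2.48 ± 0.71 (edgeR adjusted p = 0.009). MIR210 lies in an intron of MIR210HG on chromosome 11, from 568089 to 568198, and MIR205 in an exon of MIR205HG on chromosome 1, from 209432133 to 209432242. MIR203A (chromosome 14, 104117405 to 104117514) overlaps MIR203B on the other strand, and their entries held equal reads, so they are not separate measurements.

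All 6 squamous epithelial miRNAs rose in vaginal secretion, and 6 adjusted over the list alone (camera adjusted p = 5.4e-05; adjusted p = 0.378 with an estimated correlation), of which miR-944 lost its call without replicate 4 (edgeR adjusted p = 0.652), with DESeq2 (adjusted p = 0.117) and in limma voom with or without the donor block (adjusted p = 0.0504 and 0.0547). In the miR-200 family 4 of 7 rose, 5 adjusted over the list alone (camera adjusted p = 0.0206, 0.0652 without replicate 4, and also lost without replicate 1; adjusted p = 0.681 with an estimated correlation). The let-7 family had 2 of 10 members lower, 6 adjusted over the list alone, and the erythroid list 2 of 12, 2 adjusted over the list alone. Neither was called by camera (adjusted p = 0.068 and 0.0612), but both were on limma voom values, with the donor block (adjusted p = 0.0103 and 0.0221) and without it (0.0119 and 0.0175).

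In vaginal secretion 45 entries differed, 40 higher and 5 lower (edgeR), while TMMwsp gave 35 higher and 17 lower. The median log2 fold change was -0.09, which became 0.55 with RLE, -0.49 with TMMwsp and 0.15 with library size alone.

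Semen held miRNAs that were hardly read elsewhere. miR-888-5p, a product of an epididymal miRNA cluster on the X chromosome, had 16 to 201 reads in each of the 5 semen libraries and 0 reads in the 27 other libraries. miR-891a-5p of the same cluster averaged 6628 ± 6306 CPM (SD, n = 5, both semen groups) against 61 in feces, the next fluid. It was higher than the mean of the other fluids (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 6.4e-15) and than each of them (largest edgeR adjusted p = 0.000149). miR-148a-3p averaged 350610 ± 181500 CPM and rose by 3.66 ± 0.46 on the log2 scale (SE; edgeR adjusted p = 7.6e-09), and miR-200a-3p and miR-375 rose by 5.03 ± 0.47 and 4.74 ± 0.49 (edgeR adjusted p = 6.9e-12 and 8.1e-11). The myeloid miRNA miR-223-3p and the smooth muscle miRNA miR-143-3p had log2 fold changes of -5.07 ± 0.94 and -4.80 ± 1.02 (edgeR adjusted p = 2.1e-05 and 0.000148). MIR888 (145994784 to 145994860), MIR892A (145996669 to 145996743) and MIR891A (146027794 to 146027872) lie on chromosome X.

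All 3 tested epididymal miRNAs rose in semen, and 3 adjusted over the list alone (camera adjusted p = 0.000118; adjusted p = 0.312 with an estimated correlation), although miR-888-5p and miR-892a were not called by DESeq2 (adjusted p = 0.137 and 0.0601). All 7 members of the miR-200 family rose, and 7 adjusted over the list alone (camera adjusted p = 0.00026; adjusted p = 0.477 with an estimated correlation). In the erythroid list 10 of 12 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000769; adjusted p = 0.613 with an estimated correlation). All 4 endothelial and platelet miRNAs fell, 4 adjusted over the list alone, without a list call (camera adjusted p = 0.127), and miR-126-3p lost its call without vasectomized semen replicate 1 or 2 (edgeR adjusted p = 0.0612 and 0.0802). In the stromal list 4 of 6 fell, 4 adjusted over the list alone (camera adjusted p = 0.128). Of 7 kidney miRNAs 5 rose in semen and of 6 HOX cluster miRNAs 4, with the same counts adjusted over each list alone, without a list call (camera adjusted p = 0.0512 and 0.123).

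In semen 120 entries differed, 62 higher and 58 lower (edgeR), and all 62 higher and 47 of the lower calls were made under all 4 scalings. RLE gave 76 higher and 47 lower, and moved the median log2 fold change from -0.57 to -0.06, while TMMwsp moved it to -0.44.

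Saliva held raised miR-223-3p and miR-143-3p. miR-223-3p, which marks neutrophils and monocytes, averaged 53403 ± 35783 CPM (SD, n = 4) and rose by 5.94 ± 0.51 on the log2 scale over the other fluids (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 7.7e-13). miR-143-3p averaged 28999 ± 29863 CPM and rose by 4.33 ± 0.57 (edgeR adjusted p = 1.5e-07). miR-1246, an entry that resembles a small nuclear RNA, rose by 4.12 ± 0.61, and miR-205-5p by 2.72 ± 0.63 to 12037 ± 419 CPM (edgeR adjusted p = 1.8e-06 and 0.0015). miR-10a-5p was lower at -4.40 ± 0.95 and miR-320b at -3.97 ± 0.99 (edgeR adjusted p = 0.00067 and 0.0035). MIR223 lies on chromosome X, from 66018870 to 66018979, over an exon of the antisense gene AL034397.3.

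Of 6 stromal miRNAs 3 rose in saliva, 4 adjusted over the list alone (camera adjusted p = 0.00218; adjusted p = 0.508 with an estimated correlation). In the squamous list 1 of 6 rose, 4 adjusted over the list alone (camera adjusted p = 0.00817; adjusted p = 0.568 with an estimated correlation). Of 6 miRNAs of the HOX clusters 2 fell, 2 adjusted over the list alone (camera adjusted p = 0.021, and 0.0598 without saliva replicate 2; adjusted p = 0.568 with an estimated correlation), and 1 of 4 miR-320 members fell, 2 adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.568 with an estimated correlation). In the leukocyte list 3 of 10 rose, 3 adjusted over the list alone, without a list call (camera adjusted p = 0.0515).

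In saliva 28 entries differed, 21 higher and 7 lower (edgeR), and 16 did without saliva replicate 2, the deepest. The other scalings called more: RLE 47 (41 higher, 6 lower), TMMwsp 44 (42 higher, 2 lower) and library size alone 49 (46 higher, 3 lower), with the median log2 fold change going from -0.23 to 0.11, 0.42 and 0.40.

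Urine held raised miRNAs of the kidney and of the HOX clusters. The kidney miRNA miR-204-5p averaged 4348 ± 4524 CPM (SD, n = 4) against 128 in semen, the next fluid. It was higher than the mean of the other fluids (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 4.4e-13) and than each of them (largest edgeR adjusted p = 0.000607). miR-10b-5p and miR-10a-5p, whose genes lie in introns of HOXD3 and HOXB3 in the HOX clusters, averaged 107080 ± 88947 and 59367 ± 55657 CPM and rose by 6.47 ± 0.54 and 5.61 ± 0.48 on the log2 scale (SE; edgeR adjusted p = 3.1e-13 for both). miR-30a-3p averaged 8983 ± 6777 CPM against 1055 in semen (edgeR adjusted p = 4.4e-13 over the mean of the other fluids, and at most 0.0011 against each). miR-19b-3p was lower, with 0 to 4 reads in the urine libraries and a log2 fold change of -3.68 ± 0.82 (edgeR adjusted p = 0.000199). Replicates 1 to 4 held 37, 423, 538 and 0 reads of miR-204-5p, and replicate 4 also held 0 reads of miR-30a-3p and 7 each of miR-10b-5p and miR-10a-5p. On GRCh38 MIR204 lies in an intron of TRPM3 on chromosome 9 (70809975 to 70810084), MIR10B on chromosome 2 (176150303 to 176150412) and MIR10A on chromosome 17 (48579838 to 48579947).

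Of 7 kidney miRNAs 6 rose in urine, 6 adjusted over the list alone (camera adjusted p = 0.00111; adjusted p = 0.378 with an estimated correlation). All 6 HOX cluster miRNAs rose, 6 adjusted over the list alone (camera adjusted p = 0.00514, and 0.0974 without urine replicate 3; adjusted p = 0.508 with an estimated correlation). Of 20 entries that resemble rRNA, tRNA or repeats 17 rose, 18 adjusted over the list alone, among them miR-4488 at 6.75 ± 0.57 and miR-3960 at 6.68 ± 0.56 (camera adjusted p = 0.000416; adjusted p = 0.378 with an estimated correlation). In the gut and liver list 3 of 5 rose, 4 adjusted over the list alone, and in the let-7 family 5 of 10, 5 adjusted over the list alone, without a list call (camera adjusted p = 0.431 and 0.804). All 4 miR-320 members rose in urine, 4 adjusted over the list alone, also without a list call (camera adjusted p = 0.262), and miR-320a was not called without urine replicate 4 (edgeR adjusted p = 0.184).

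In urine 138 entries differed, 101 higher and 37 lower (edgeR). TMMwsp gave 80 higher and 50 lower and moved the median log2 fold change from 0.87 to 0.20, while RLE moved it to 1.09 and library size alone to 0.69. All 4 urine libraries, all 4 perspiration libraries and vasectomized semen replicate 2 had a ratio of miR-486 to miR-451a reads of at least 0.475, while the 23 other libraries had at most 0.127. With a term for these 9 libraries, which only the 2 vasectomized semen libraries could estimate, edgeR called 2 entries in urine. Directly against perspiration, urine differed in 57 entries, 39 higher and 18 lower, and 6 of 7 kidney miRNAs were higher in urine (edgeR).

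Feces held raised levels of a few rarely read miRNAs and of both arms of miR-144. miR-657 had 4 to 27 reads in each feces library, a mean of 2314 ± 1492 CPM (SD, n = 4), and at most 1 read in any other library (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 4e-11, but 0.118 with DESeq2). miR-192-3p, whose gene is active in gut and liver, averaged 584 ± 766 CPM from 0 to 10 reads per library (edgeR adjusted p = 6.5e-07). miR-144-3p rose by 2.94 ± 0.58 to 15210 ± 5931 CPM, and miR-144-5p by 2.46 ± 0.59 on the log2 scale (SE; edgeR adjusted p = 0.00023 and 0.0028). miR-451a had a log2 fold change of 1.23 ± 0.57 (edgeR adjusted p = 0.118), which was called with RLE, TMMwsp and library size alone (adjusted p = 0.00854, 6.2e-05 and 0.000411) and in limma voom with or without the donor block (adjusted p = 0.0484 and 0.0496). let-7c-5p was lower, at -4.02 ± 0.91 (edgeR adjusted p = 0.0013, and 0.0585 with TMMwsp). miR-1246 was carried by 1 library: its log2 fold change of 4.68 ± 0.62 became -1.09 without feces replicate 2 (edgeR adjusted p = 0.422), and it was not called in limma voom with or without the donor block (adjusted p = 0.247 and 0.302). MIR657 lies in an intron of AATK on chromosome 17 (81125276 to 81125373) and MIR192 in an exon of MIR194-2HG on chromosome 11 (64891137 to 64891246).

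In the erythroid list 2 of 12 rose in feces, 2 adjusted over the list alone, and RLE, TMMwsp and library size alone gave 6, 11 and 8 higher (camera adjusted p = 0.000315, and in limma voom 0.17 with and 0.167 without the donor block; adjusted p = 0.568 with an estimated correlation). In the gut and liver list only miR-192-3p rose, 1 of 5 and 1 adjusted over the list alone (camera adjusted p = 0.272). The let-7 family had 3 of 10 lower, 3 adjusted over the list alone (camera adjusted p = 0.46), with a median of -0.99 that became 0.71 with TMMwsp.

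In feces 60 entries differed, 20 higher and 40 lower (edgeR), but the direction depended on scaling: RLE gave 33 higher and 13 lower, TMMwsp 54 higher and 0 lower, and library size alone 41 higher and 3 lower, and the median log2 fold change of -0.86 became -0.19, 0.91 and 0.39. Of the 20 higher calls 19 were made under all 4 scalings, of the 40 lower calls 0. Without 1 feces library the counts were 32, 27, 38 and 30 for replicates 1 to 4. Feces libraries held 1413 to 3597 reads, so absence from feces was not measurable for most entries.

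Perspiration held raised miR-203a and miR-320 family miRNAs. miR-203a, a miRNA of the differentiating epidermis, averaged 190800 ± 84380 CPM (SD, n = 4) and rose by 4.96 ± 0.51 on the log2 scale (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 5.4e-11). miR-320c averaged 10080 ± 4413 CPM against 831 in urine, the next fluid (largest edgeR adjusted p against a single fluid = 0.00266). Over the mean of the other fluids miR-320c was higher (edgeR adjusted p = 8.1e-15), and miR-320b rose by 5.29 ± 0.49 (edgeR adjusted p = 5e-12). miR-1290 rose by 6.30 ± 0.56 to 15563 ± 8315 CPM (edgeR adjusted p = 2e-12), and miR-205-5p by 3.25 ± 0.61 (edgeR adjusted p = 3.4e-05). miR-17-5p and miR-101-3p were lower, at -4.15 ± 0.91 and -3.82 ± 0.72 (edgeR adjusted p = 0.00033 and 3.4e-05). miR-320c is encoded on chromosome 18 by MIR320C1 (21683510 to 21683597) and MIR320C2 (24321686 to 24321735), whose reads cannot be separated.

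All 4 miR-320 members rose in perspiration, 4 adjusted over the list alone (camera adjusted p = 0.000623; adjusted p = 0.401 with an estimated correlation), of which miR-320a, at 1.47 ± 0.51, was not called with TMMwsp, library size alone or without perspiration replicate 4 (edgeR adjusted p = 0.13, 0.0658 and 0.0562). Of 20 entries that resemble rRNA, tRNA or repeats 16 rose, 16 adjusted over the list alone (camera adjusted p = 9.9e-05; adjusted p = 0.378 with an estimated correlation). In the squamous list 4 of 6 rose, 5 adjusted over the list alone (camera adjusted p = 0.0448, and 0.0756 with RLE; adjusted p = 0.709 with an estimated correlation), a call that was lost without any of 23 of the 32 libraries, with the largest adjusted p of 0.0803 without vasectomized semen replicate 2. The 4 miR-320 members also rose in urine without a list call, and vasectomized semen replicates 2 and 1 held 435 and 56.0 CPM of miR-320c. Perspiration, urine and vasectomized semen replicate 2 shared a high ratio of miR-486 to miR-451a. In the kidney list 0 of 7 were called, and 0 adjusted over the list alone (camera adjusted p = 0.876).

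In perspiration 99 entries differed, 65 higher and 34 lower (edgeR). RLE gave 89 higher and 21 lower and moved the median log2 fold change from 0.04 to 0.87, and TMMwsp gave 55 higher and 46 lower and moved it to -0.21. With the term for the 9 libraries with a high ratio of miR-486 to miR-451a, edgeR called 0 entries in perspiration, against 118 of 247 at an unadjusted p under 0.05 without the term; limma voom without the term called 101 and DESeq2 97.

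**Figure D3:**
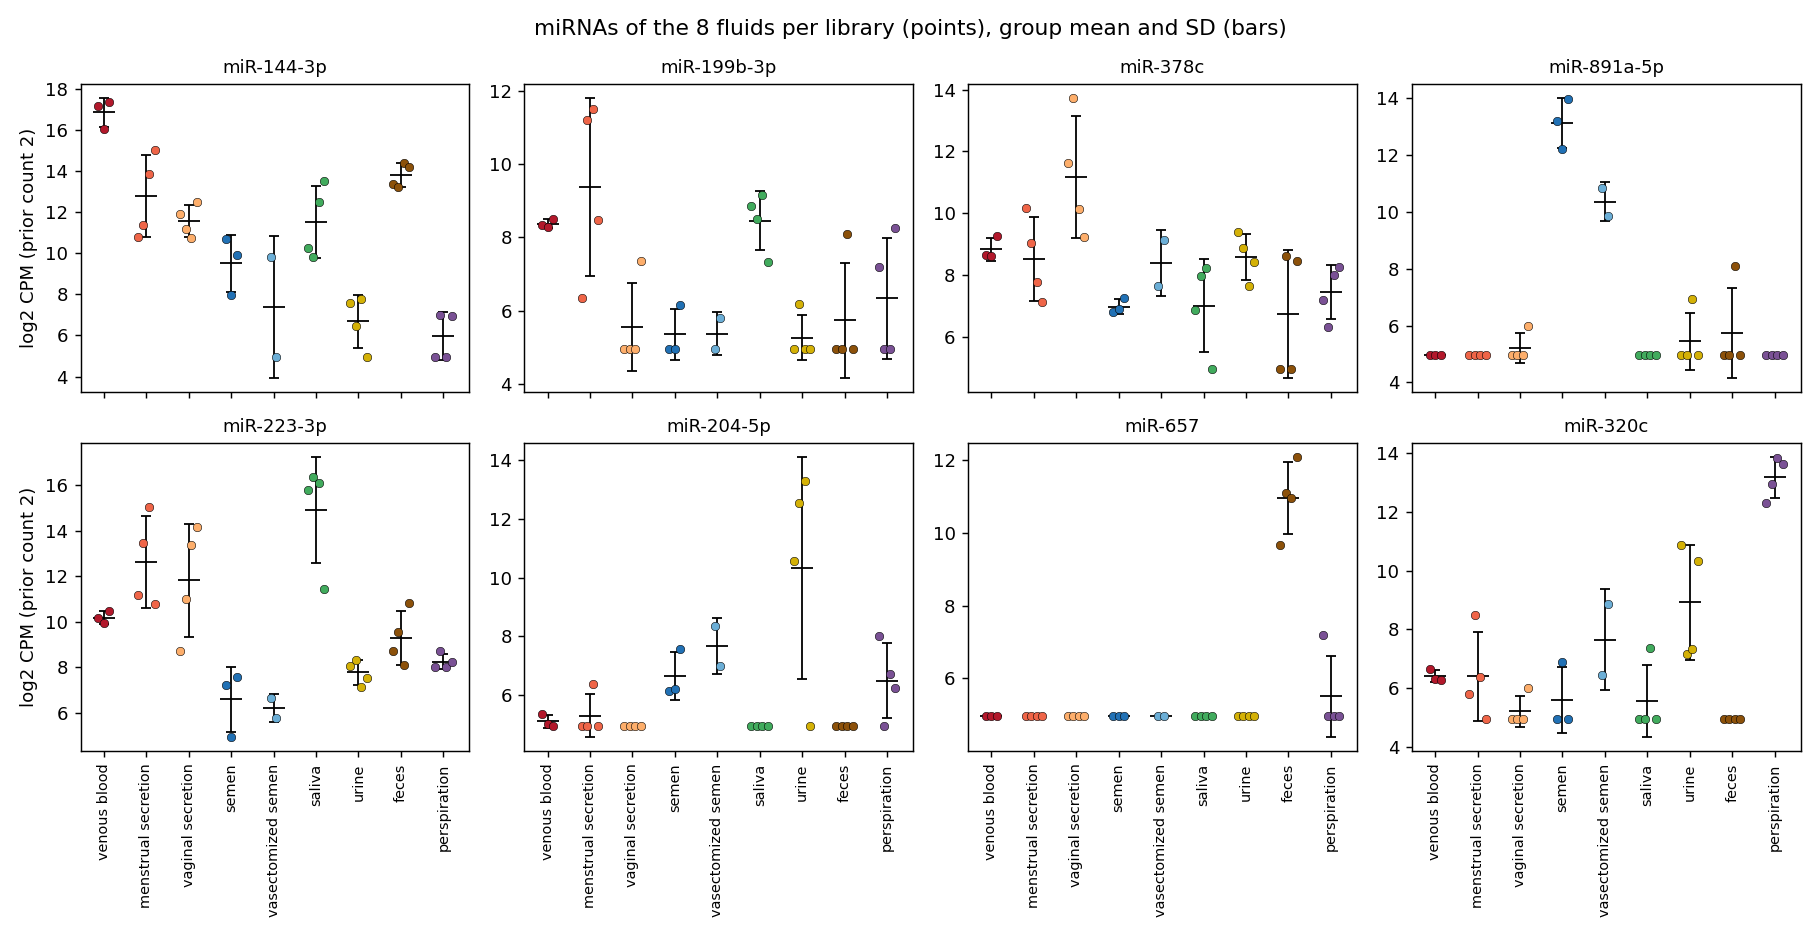
log2 CPM (prior count 2) of 8 miRNAs, 1 per panel (y axis), in the 8 fluids (x axis). Points are libraries and bars the mean ± SD; libraries with 0 reads sit at the lowest level. miR-378c is highest in vaginal secretion at a mean of 4609 CPM, miR-204-5p in urine at 4348 CPM, miR-657 in feces at 2314 CPM and miR-320c in perspiration at 10080 CPM.

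A miRNA was counted as specific to a fluid when it was higher there than in each of the 7 other fluids (edgeR adjusted p under 0.05 in every comparison). Blood had 30 such miRNAs, urine 13, semen 8, feces 5, perspiration 4, vaginal secretion 1, and menstrual secretion and saliva 0. Ranked by the smallest of the 7 folds, blood was led by miR-17-5p, 3.38 on the log2 scale above menstrual secretion, miR-144-3p, 3.07 above feces, and miR-126-3p, 3.04 above feces (largest edgeR adjusted p = 0.00191, 0.0128 and 0.00714). The semen miRNAs were miR-888-5p, miR-891a-5p, miR-135a-5p, miR-125b-2-3p, miR-141-3p, miR-155-5p, miR-200a-3p and miR-148a-3p, the last 2.01 above saliva. Urine had miR-204-3p, miR-204-5p and miR-1307-3p at the top, and miR-1307-3p was 3.65 above perspiration. In feces they were miR-657, miR-192-3p, miR-452-3p, miR-6777-5p and miR-7706, and in perspiration miR-320c (3.68 above urine), miR-24-2-5p, miR-4448 and miR-320b. The vaginal miRNA was miR-378c, 3.18 above menstrual secretion (edgeR adjusted p = 0.0315).

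These counts were sensitive. Blood had 0 specific miRNAs with RLE, TMMwsp, library size alone and DESeq2 and 40 with the donor block in limma voom, and 8 to 19 without semen replicate 1, urine replicate 3, perspiration replicate 2 or 3, saliva replicate 1 or 4, vaginal replicate 2 or blood replicate 1 or 3 (8, 9, 18, 10, 14, 18, 17, 19 and 17). Vaginal secretion had 0 with RLE and 3 with library size alone. Its 1 miRNA was lost without menstrual secretion replicate 3 or 4, perspiration replicate 3, saliva replicate 1, 2 or 4, semen replicate 1 or 2, urine replicate 3, vaginal replicate 1 or 2, or any library of vasectomized semen or blood, and the count was 4 without menstrual secretion replicate 1 and 3 without vaginal replicate 4. Urine had 4 with TMMwsp and 6 with the donor block, and 5 to 8 without feces replicate 4, perspiration replicate 3, saliva replicate 1 or 4, semen replicate 1 or 3, urine replicate 1, 3 or 4, vaginal replicate 2 or vasectomized semen replicate 1. Feces had 0 with DESeq2, 1 without saliva replicate 2, 2 without feces replicate 4 and 3 without feces replicate 2 or 3, menstrual secretion replicate 2, 3 or 4, semen replicate 3, urine replicate 2 or 4, vaginal replicate 1, 2 or 3, or either vasectomized semen library. Perspiration had 2 with TMMwsp, with library size alone and without perspiration replicate 2, 1 without perspiration replicate 4, and 8 and 7 without vasectomized semen replicates 1 and 2. Menstrual secretion had 0 under all alternatives, DESeq2 and limma voom included, and saliva had 1 with DESeq2, with library size alone and without menstrual secretion replicate 3 and 0 with limma voom.

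Menstrual secretion was compared with venous blood, since both hold blood. Epithelial miRNAs were far higher in menstrual secretion: miR-200a-3p averaged 9973 ± 11107 CPM (SD, n = 4) against 8 ± 14 in blood (SD, n = 3), a log2 fold change of 10.01 ± 1.40 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 7.8e-07). The squamous miRNAs miR-203a and miR-205-5p rose by 9.97 ± 1.47 and 9.62 ± 1.66 (edgeR adjusted p = 1.05e-06 and 1.4e-05). miR-363-3p, a red cell miRNA, was lower, with 2098 ± 2230 CPM against 31558 ± 8968 and a log2 fold change of -3.92 ± 0.82 (edgeR adjusted p = 0.0002), and miR-484 was lower at -4.67 ± 0.84 (edgeR adjusted p = 2.2e-05). All 6 squamous and all 7 miR-200 family miRNAs rose, with the same counts adjusted over each list alone (camera adjusted p = 2.2e-05 and 5.4e-05; adjusted p = 0.378 and 0.401 with an estimated correlation). In the erythroid list 9 of 12 fell, and adjusted over the list alone 10 fell and 1 rose (camera adjusted p = 0.000917; adjusted p = 0.613 with an estimated correlation), while RLE left 2 lower and 1 higher.

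Between menstrual secretion and blood 120 entries differed, 63 higher and 57 lower (edgeR). RLE gave 109 higher and 8 lower and moved the median log2 fold change from 0 to 2.07, and library size alone gave 81 higher and 33 lower with a median of 0.81, and TMMwsp moved the median to 0.19. All 63 higher calls but only 8 of the lower ones were made under all 4 scalings.

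Menstrual secretion was compared with vaginal secretion, with which it shares epithelium. Among entries read in both fluids the largest rises were in the stromal miRNAs miR-199b-3p, 4.55 ± 1.18, and miR-199a-3p, 3.99 ± 1.15, and in the red cell miRNA miR-16-2-3p, 4.10 ± 0.97 (log2 fold change ± SE, n = 4 each; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.031, 0.048 and 0.025). miR-199a-5p was also called (edgeR adjusted p = 0.048), from 1 to 44 reads per menstrual library against 0 in every vaginal library, so no fold is given. miR-451a averaged 283250 ± 342100 CPM against 34648 ± 14786, and rose by 3.03 ± 0.90 (edgeR adjusted p = 0.048). miR-378c was the 1 entry that was lower, at -3.18 ± 0.85 (edgeR adjusted p = 0.031). Of 6 stromal miRNAs 3 rose, 5 adjusted over the list alone (camera adjusted p = 0.00248; adjusted p = 0.508 with an estimated correlation), and of 12 erythroid miRNAs 2 rose, 8 adjusted over the list alone (camera adjusted p = 0.0023, and 0.0772 without menstrual secretion replicate 4; adjusted p = 0.675 with an estimated correlation). The let-7 family, with 2 of 10 higher and 3 adjusted over the list alone, was not called (camera adjusted p = 0.0839) but was on limma voom values with or without the donor block (adjusted p = 0.0221 and 0.0274).

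Only 8 entries differed between these fluids, 7 higher and 1 lower (edgeR), against 57 at an unadjusted p under 0.05, and none of the 8 calls was stable. RLE called 0, DESeq2 5, library size alone 10 (3 higher, 7 lower) and limma voom 2 with the donor block and 1 without it. With the block miR-199b-3p, miR-199a-3p, miR-378c and miR-451a had limma voom adjusted p = 0.0558, 0.0691, 0.0558 and 0.118, and without it 0.0665, 0.0749, 0.0665 and 0.142. RLE moved the median log2 fold change from 0.42 to -0.18 and library size alone to 0. Leaving out 1 library gave 0 without menstrual secretion replicate 3 or 4, vaginal replicate 1 or 2, or any library of vasectomized semen or blood, 1 to 4 without vaginal replicate 3, urine replicate 2, 3 or 4, semen replicate 1 or 2, perspiration replicate 3 or any library of saliva or feces, and 15, 20 and 29 without menstrual secretion replicate 2, vaginal replicate 4 and menstrual secretion replicate 1.

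Vasectomized semen was compared with semen, a comparison that bears on the part of semen that the vas deferens carries. miR-34c-5p, a miRNA of male germ cells and of multiciliated cells, averaged 28 ± 20 CPM in vasectomized semen (SD, n = 2) against 7874 ± 1204 in semen (SD, n = 3), and fell by 7.92 ± 1.35 on the log2 scale (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2e-04). It had 1 and 7 reads in the vasectomized libraries, both deeper than every semen library, and at least 163 in each semen library. The testicular cluster miRNA miR-514a-3p had 0 reads in vasectomized semen and 60 in semen, 811 ± 820 CPM (SD, n = 3), and miR-509-3-5p of the same cluster had 1 read in vasectomized semen and 66 in semen (edgeR adjusted p = 0.00099 and 0.0087). miR-122-5p and miR-3591-3p, which share all their reads, fell by 5.82 ± 1.39 (edgeR adjusted p = 0.0087). MIR34C lies on chromosome 11 (111513439 to 111513515), and MIR509-3 (147259652 to 147259726) and MIR514A1 (147279247 to 147279344) on chromosome X.

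Of the epididymal list 0 of 3 members were called over all entries and 3 were lower adjusted over the list alone: miR-888-5p at -4.08 ± 1.27, miR-892a at -3.39 ± 1.24 and miR-891a-5p at -2.90 ± 1.04 (edgeR adjusted p = 0.107, 0.146 and 0.141 over all entries). In limma voom miR-888-5p and miR-892a were called with the donor block (adjusted p = 0.0246 and 0.028) and without it (0.0226 and 0.0258). The list was called by camera (adjusted p = 7.6e-08; adjusted p = 0.0263 with an estimated correlation). Both tested testicular miRNAs fell, 2 adjusted over the list alone, too few for a list test. Against other fluids 0 were called in semen (1 higher over the list alone). There miR-514a-3p could not be called, with 0 vasectomized reads. It was called in urine (0 to 24 reads, edgeR adjusted p = 1.05e-05) and vaginal secretion (1 to 2 reads, 0.041, lost with TMMwsp). Semen held 176 to 1737 CPM, urine up to 337. The miR-320 family, with 0 of 4 called and 3 higher adjusted over the list alone, had camera adjusted p = 0.0498, which was 0.577 without vasectomized semen replicate 2, was lost without any of 20 libraries and with RLE (0.0751), and in limma voom was 0.0678 with and 0.0662 without the donor block (adjusted p = 0.613 with an estimated correlation).

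In all 5 entries were lower and 0 higher under each of the 4 scalings (edgeR), against 38 at an unadjusted p under 0.05, with 2 called by DESeq2 and 8 by limma voom with or without the donor block. Without semen replicate 1 or vasectomized semen replicate 2 only 1 entry was called, and 3 without semen replicate 3. miR-34c-5p was called without any of the 32 libraries in turn, whereas miR-514a-3p, miR-509-3-5p and miR-122-5p were not called without vasectomized semen replicate 2 (edgeR adjusted p = 0.226, 0.344 and 0.405). The median log2 fold change of 0.28 became 0.02 with RLE, 0.13 with TMMwsp and 0 with library size alone.

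**Figure D4:**
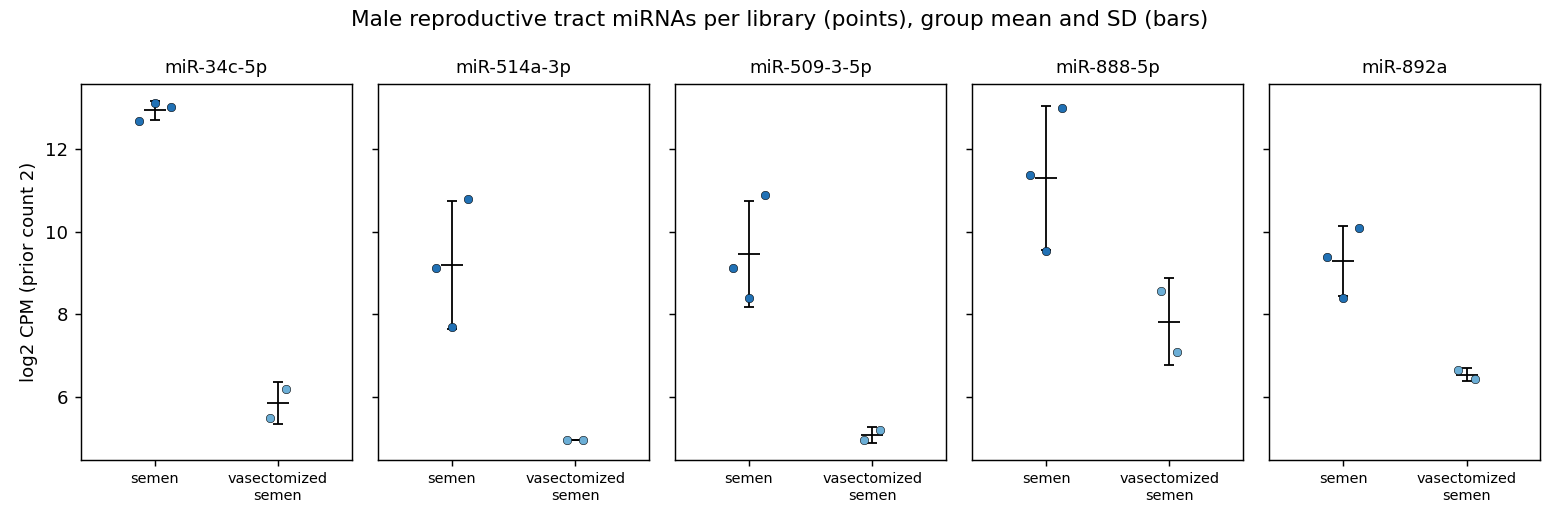
log2 CPM (prior count 2, y axis) of 5 miRNAs in semen (n = 3) and vasectomized semen (n = 2) (x axis), with points for libraries and bars for the mean ± SD. For miR-34c-5p every vasectomized library lies below every semen library, with 1 and 7 reads against at least 163.

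Saliva was compared with vaginal secretion, another fluid over a squamous epithelium. miR-1246 was higher in saliva, with a log2 fold change of 4.92 ± 1.25 (SE, n = 4 each; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.01), and miR-210-3p was lower, at -5.68 ± 1.10 (edgeR adjusted p = 0.001). These calls held without any of the 32 libraries in turn. miR-452-5p, miR-378c and miR-193b-3p were lower at -5.43 ± 1.24, -4.84 ± 0.96 and -4.80 ± 1.09, and lost their calls without vaginal replicate 2 (edgeR adjusted p = 0.0729, 0.0873 and 0.0519). The stromal list was called with 0 of 6 members called, and 0 adjusted over the list alone (camera adjusted p = 0.00771; adjusted p = 0.568 with an estimated correlation). The squamous and miR-200 lists had 0 of 6 and 0 of 7 called, and 0 adjusted over each list alone (camera adjusted p = 0.253 and 0.0557).

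In all 14 entries differed, 3 higher and 11 lower (edgeR), against 55 at an unadjusted p under 0.05. RLE gave 1 higher and 17 lower, TMMwsp 20 higher and 8 lower, library size alone 8 higher and 11 lower, limma voom 26 with the donor block and 27 without it, and DESeq2 26, and the median log2 fold change of 0 became -0.10 with RLE, 0.55 with TMMwsp and 0.19 with library size alone. Without 1 library the count was 3 without vaginal replicate 2, 8 and 9 without saliva replicates 1 and 3, 22 without perspiration replicate 2 or 4 or menstrual secretion replicate 3, 27 without menstrual secretion replicate 1 and 28 without vaginal replicate 4.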

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

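All tests of explanations and all counts of other splits in this part were chosen after the results were seen.

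miR-451a, a red cell miRNA, was read 49 times or more in every library, those of fluids other than blood and menstrual secretion included. In perspiration, urine and vasectomized semen replicate 2 the reads did not decide for or against blood RNA. miR-144-3p, which follows miR-451a in blood, had 22 reads there, where the lowest ratio seen in blood would bring 888.2 (a quotient of 0.0248). Its ratio to miR-451a was 0 to 0.00664 in these libraries against 0.096 to 0.16 in blood. Of 31 abundant blood miRNAs 3 lay under 0.5 of the required reads (median quotient 4.84). Vasectomized semen replicate 2 held 0 reads of miR-144-3p beside 703 of miR-451a, and replicate 1 held 63 beside 502 (Fisher's exact test of these 2 libraries, two-sided p = 1.01e-23, counting error only). Blood RNA that lost miR-144-3p stays open, since these libraries cannot tell it from the absence of blood RNA. In feces, saliva, vaginal secretion, semen and vasectomized semen replicate 1 the same quotient was 0.863 (842 of 975 reads), so blood RNA or reads from blood libraries may have contributed there. A fixed number of stray reads per library is also open, since within 5 groups of 4 libraries miR-451a rose with the library total by a slope of only 0.287 (95% interval -0.0556 to 0.630, against a median of 1.20 and a range of 0.204 to 1.61 for 20 other abundant miRNAs). No biological explanation other than blood was tested.

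Of 20 entries that resemble rRNA, tRNA or repeats 16 rose in perspiration and 17 in urine, and 6 of 7 kidney miRNAs in urine. These 3 list calls were lost with an estimated correlation. Perspiration, urine and vasectomized semen replicate 2 shared a high ratio of miR-486 to miR-451a, and a shared preparation or run is 1 candidate cause. For the repeat-like entries it cannot be told apart from the fluids: vasectomized semen replicate 2 exceeded replicate 1 by a median of 1.27 on the log2 scale (15 of 20 higher), but this is 1 pair, and of 42 other pairs of libraries within groups 3 differed as much, by up to 2.98. These 3 were all urine pairs, inside the set with the high ratio, and the 36 pairs outside urine differed by at most 0.863. The miR-320 miRNAs also went with these libraries, with 4 of 4 higher in perspiration and, without a list call, in urine. Vasectomized semen replicates 2 and 1 held 435 and 56.0 CPM of miR-320c. No explanation was tested for them. Of 7 kidney miRNAs 6 were higher in urine than in perspiration, which shares the ratio. This argues against a shared preparation or run as sole cause. The urine kit stays open for the values of urine alone, since repeat-like entries also rose in perspiration, with another kit. The origin of urine itself was not tested.

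miR-34c-5p, miR-514a-3p and miR-509-3-5p were lower in vasectomized semen than in semen. Depth is excluded, since the lowest semen shares would bring 2033, 43.4 and 75.9 reads and 8, 0 and 1 were seen (0.00418 in all). Vasectomized replicate 1 would hold 760, 16.2 and 28.4 but held 1, 0 and 0 (0.00124). This 1 library argues against a preparation of replicate 2. Scaling is excluded, since the fold change closest to 0 under 3 other scalings was -7.45 on the log2 scale. The absence of sperm and of testicular and epididymal fluid may account for the difference, a hypothesis that no test here decides, since only 2 vasectomized libraries were compared.

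Other splits of the libraries into groups of the same sizes were compared with the real one, 100 splits drawn for the comparisons with all other fluids, the real one included. Each other split relabeled all 9 groups at once, so its groups mixed libraries of different fluids. A low share therefore speaks against arbitrary labels as a whole, not against chance in 1 fluid. The shares were not adjusted over the comparisons. Only the real split gave as many calls for blood (124 calls, highest other split 36), vaginal secretion (45, 32), semen (120, 30), urine (138, 71), feces (60, 56) and perspiration (99, 50). For menstrual secretion 2 of 100 splits gave 67 calls or more (highest other 75). Chance cannot be excluded for saliva, where 6 of 100 splits gave 28 calls or more (highest other 56). Specific miRNAs were found only in the real split, 1 of 100, for blood (30), vaginal secretion (1), semen (8), urine (13), feces (5) and perspiration (4), and the highest other split had 0. A miRNA specific to 1 of several mixed groups is unlikely by construction, so these shares add little. For menstrual secretion and saliva, with 0 specific miRNAs, 100 of 100 splits had as many. For the 31 list calls chance cannot be excluded, since 60 of 100 splits gave as many or more (highest other 51).

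Of the 35 splits of each pair of groups, only the real one gave as many calls as the 120 of menstrual secretion against blood, though another gave 110. A share of 1 of 35 is the smallest these splits allow. Chance cannot be excluded for menstrual against vaginal secretion, where 5 of 35 splits gave 8 calls or more, and the highest other, 48 calls, points to a structure of the libraries, which was not examined. Nor can it for saliva against vaginal secretion, where 2 of 35 gave 14 calls or more (highest other 17). Vasectomized semen was not split, since groups of 2 and 3 allow 10 splits, too few for a share under 0.05.

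Single libraries that stood far from the other 3 of their group were sought by Dixon's ratio of the gap to the range over 109 measures. The ratio passed the 95% limit in 19 of them, where chance, which does so in about 1 of 20 groups, would give 5.45. The following values were picked out in this way, with the ratio after each. Feces replicate 2 held 28.8% miR-451a against 39.2% to 40.1% in the others (0.914) and 26.1% miR-1246 against 0.0466% to 0.167% (0.995). Menstrual secretion replicate 4 held 5.72% miR-21-5p against 25.8% to 29.2% (0.854) and 2268 CPM of miR-8086 against 106.4 to 448 (0.842), and replicate 3 held 1170 CPM of miR-199a-5p against 24.9 to 166 (0.876). Perspiration replicate 4 held 915 CPM of miR-24-2-5p against 380 to 459 (0.851). Saliva replicate 2 held 48970 reads against 4043 to 6476 (0.946) and 135 entries with at least 10 reads against 57 to 65 (0.897), and saliva replicate 4 held 5.05% miR-21-5p against 14.7% to 15.5% (0.921).

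In urine replicate 4 miR-375 made up 16.5% against 0.493% to 2.64% (0.865), miR-4532 reached 4056 CPM against 18.6 to 479 (0.886) and miR-4488 19660 against 701 to 1796 (0.942). In urine replicate 1 miR-30c-2-3p reached 2355 CPM against 687 to 965 (0.833). Vaginal secretion replicate 4 held 35690 reads against 4277 to 8262 (0.873), more entries with at least 10 reads than the 61 to 66 of the others (0.918) and 58970 CPM of miR-205-5p against 15930 to 19930 (0.907). Vaginal secretion replicate 2 held 30830 CPM of miR-210-3p against 4812 to 7223 (0.907) and 1487 CPM of miR-378d against 166 to 391 (0.830), and replicate 1 held 1563 CPM of miR-184 against 33.2 to 270 (0.845).

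Skeletal muscle miRNAs were picked out as a signal outside the tested entries, because all 5 in the table were too low to be tested. Perspiration replicate 4 held 105 reads of miR-1, 135 of miR-133a-3p, 18 of miR-133b and 58 of miR-206, while no other library held more than 24, 2, 1 and 12. The highest count of miR-499a-5p was 16.1 reads in blood replicate 1, against 12.2 in the next library.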

How the results depend on the processing

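The settings chosen after seeing the data are thinning, leaving out libraries under 5000 reads, leaving out or adding a term for the 9 libraries with a high ratio of miR-486 to miR-451a, and 1 entry per sharing set. Counts of calls stayed within 1.5 times except as given here, but their direction turned with scaling: feces went from 20 higher and 40 lower to 54 and 0 with TMMwsp, blood from 92 and 32 to 21 and 73 with RLE, menstrual secretion against blood from 63 and 57 to 109 and 8 with RLE, menstrual against vaginal secretion from 7 and 1 to 3 and 7 with library size alone, and saliva against vaginal secretion from 3 and 11 to 20 and 8 with TMMwsp. The cause of these changes was not tested, except that thinning and left-out libraries reduce reads or samples by construction.

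Among scalings, RLE called 47 entries in saliva and 0 in menstrual against vaginal secretion, and 0 specific miRNAs in blood and in vaginal secretion. TMMwsp called 44 in saliva and 28 in saliva against vaginal secretion, with specific counts of 0 in blood, 4 in urine and 2 in perspiration. Library size alone called 49 in saliva, with 0 specific in blood, 3 in vaginal secretion, 1 in saliva and 2 in perspiration. Without a filter, calls were 325 in blood, 39 in feces, 182 in menstrual secretion against blood, 0 in menstrual against vaginal secretion, 9 in vasectomized semen and 4 in saliva against vaginal secretion, with 0 specific in vaginal secretion, 5 in semen, 5 in urine and 8 in feces, and 49 list calls. A filter of 100 CPM in 3 libraries gave 0 in menstrual against vaginal secretion, 10 in vasectomized semen, and 0 specific in vaginal secretion, 7 in urine and 7 in perspiration.

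DESeq2 called 44 in menstrual secretion, 5 in menstrual against vaginal secretion, 2 in vasectomized semen and 26 in saliva against vaginal secretion, with specific counts of 0 in blood, 1 in saliva and 0 in feces. limma voom called 25, 1, 8 and 27 in these 4 comparisons, with 0 specific in vaginal secretion and 6 in urine. The fluids of the Qiagen kit alone gave 44 in saliva, 8 in vasectomized semen and 23 in saliva against vaginal secretion, and 10 specific in blood, 14 in semen, 1 in saliva and 13 in perspiration. An estimated correlation left 1 list call and fry gave 55.

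With the donor as a replicate block, limma voom called 31 in menstrual secretion, 2 in menstrual against vaginal secretion, 8 in vasectomized semen and 26 in saliva against vaginal secretion, with 6 specific in urine. Of 225 named results 17 lost and 4 gained their call with the block, and these 21 and the list changes given in the report also occurred in limma voom without the block, so they came with the tool. Without the block miR-144-3p, miR-944 and miR-200a-3p in menstrual secretion also lost it (0.0627, 0.0548 and 0.0515) and miR-203a in saliva gained it (0.0466). Besides those given in the report, miR-126-3p (0.299) in menstrual secretion, miR-204-5p in semen (0.207), miR-30a-3p in feces (0.202), miR-199a-5p (0.199), let-7i-5p (0.0558) and let-7f-5p (0.118) in menstrual against vaginal secretion, and miR-320a in saliva against vaginal secretion (0.0557) lost it, and miR-944 in saliva gained it (0.0393), all limma voom adjusted p. List tests with the block gave 32 calls, 29 of them shared with the 31, and pairs of different donors alone a similarity of 0.239. Compared with limma voom without it, the block changed no other call of a named miRNA and no list call.

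Thinning every library to 1416 reads left 31 calls in blood, 18 in menstrual secretion, 18 in vaginal secretion, 34 in semen, 17 in saliva, 33 in urine, 18 in feces and 27 in perspiration, 20 in menstrual secretion against blood, 3 in menstrual against vaginal secretion and 0 in vasectomized semen, with 0 specific in blood, 2 in semen, 6 in urine, 0 in feces and 1 in perspiration. Without libraries under 5000 reads there were 0 calls in menstrual against vaginal secretion and 1 in saliva against vaginal secretion, and 0 specific in vaginal secretion. Without the 9 high-ratio libraries there were 37 in menstrual secretion, 81 in vaginal secretion, 1 in vasectomized semen and 25 in saliva against vaginal secretion, and 2 specific in vaginal secretion and 14 in semen. With a term for them there were 15 in menstrual secretion, 19 in vaginal secretion, 9 in saliva, 2 in urine, 14 in feces, 0 in perspiration and 1 in vasectomized semen, and 13 specific in blood, 0 in vaginal secretion, 1 in semen and 0 in urine, feces and perspiration. With 1 entry per sharing set there were 3 in menstrual against vaginal secretion and 8 specific in urine and 3 in feces.

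Leaving out 1 library at a time gave ranges of 95 to 130 in blood, 25 to 73 in menstrual secretion, 32 to 56 in vaginal secretion, 94 to 124 in semen, 16 to 42 in saliva, 27 to 65 in feces, 82 to 120 in perspiration, 91 to 131 in menstrual secretion against blood, 0 to 29 in menstrual against vaginal secretion, 1 to 6 in vasectomized semen and 3 to 28 in saliva against vaginal secretion, and kept urine within 1.5 times its count. Specific miRNAs went from 8 to 36 in blood, 0 to 0 in menstrual secretion, 0 to 4 in vaginal secretion, 6 to 9 in semen, 0 to 1 in saliva, 5 to 14 in urine, 1 to 5 in feces and 1 to 8 in perspiration, list calls from 27 to 38 and the similarity from 0.209 to 0.255. Where vasectomized semen kept 1 library, it was assumed to vary like the other groups.

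Of the 225 named results, 191 kept direction and call with RLE, 202 with library size alone, 180 with DESeq2, where 3 had no adjusted p, 83 of 120 after thinning and 124 with the high-ratio term. TMMwsp ended the call of 14, no filter that of 31, and leaving out any 1 library that of at most 25. Reversed were miR-1246 in feces without feces replicate 2 (-1.09, with up to 5.32 without other libraries), miR-34c-5p in vaginal secretion after thinning (-1.09), and, with the high-ratio term, miR-144-3p in urine (2.41) and perspiration (1.30) and miR-320a in perspiration (-0.41), none of them called.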

Other observations

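The miRNAs and the comparison of urine with perspiration in this part were chosen after their values were seen.

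Several male tract miRNAs, most of them too low to be tested, had more reads in semen than in vasectomized semen. Summed over the libraries, miR-34b-3p, which shares a transcript with miR-34c, had 17 reads in semen and 1 in vasectomized semen, or 229 against 3.41 CPM (here of the summed library totals, before TMM scaling). miR-449a, a relative of miR-34, had 12 reads against 0 (162 against 0 CPM), and miR-508-3p of the testicular cluster 17 against 1 (229 against 3.41). In the epididymal cluster miR-891a-5p had 745 reads against 278 (10040 against 947 CPM), miR-892c-3p 27 against 13 (364 against 44.3) and miR-890 11 against 3 (148 against 10.2). miR-888-3p, with 2 reads against 11 (26.9 against 37.5 CPM), was too low to order. Over both vasectomized libraries, reads of the epididymal cluster were present while miR-514a-3p and miR-449a had 0. miR-34c-5p, the 1 tested member of the germ and multiciliated cell list, was also higher in menstrual and in vaginal secretion than the log-scale mean of the other fluids, which includes feces and perspiration with 0 reads in every library. It averaged 421 ± 336 and 214.9 ± 254 CPM there (SD, n = 4 each; edgeR adjusted p = 5.5e-06 and 0.00123), below the 7874 ± 1204 of semen (SD, n = 3), with only 2 to 34 and 0 to 11 reads per library.

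Urine and perspiration differed directly in 57 of 247 entries, 39 higher and 18 lower in urine (edgeR). In urine 5 of 6 HOX cluster miRNAs, 6 of 7 kidney miRNAs and 3 of 5 gut and liver miRNAs were higher, with miR-10b-5p at 6.79 ± 1.15 and miR-10a-5p at 6.07 ± 1.00 on the log2 scale (SE; edgeR adjusted p = 5.9e-05 for both). In perspiration 3 of 6 squamous epithelial entries, 2 of them equal, and 2 of 4 miR-320 miRNAs were higher. Of 20 repeat-like entries 4 were higher in urine and 0 in perspiration. In semen the leukocyte list went both ways, with 3 of 10 members higher and 5 lower: miR-155-5p rose by 2.85 ± 0.52 and miR-146a-5p by 1.82 ± 0.45 on the log2 scale, while miR-142-3p stood at -5.81 ± 0.88 (SE; edgeR adjusted p = 1.8e-05, 0.000978 and 6.4e-07).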
